A study of Mus musculus with 2 samples.

How the data were processed

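H3K4me3 ChIP-seq was performed on mouse neural tube (strain B6NCrl) at embryonic day 12.5, per the labels, with 2 biological replicates from separate pools of 120 and 88 embryos of mixed sex and libraries of 300 to 500 bp. Each replicate has its own peak list, and 2 further lists cover the series: peaks called on both replicates together and replicated peaks. Per the text files deposited with the samples, the lists are on the mm10 assembly, each replicate's list derives from its filtered alignments and 1 further file whose kind is not stated, and the replicated list derives from the pooled list and both replicates' lists. The labels name a possible control experiment. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. The lowest −log10 p was 2.01 in replicate 1, 2.00 in replicate 2, 2.04 in the pooled list and 2.42 in the replicated list. The lowest −log10 q was 0.181, 0.128, 0.224 and 0.537 in the same order, so the lists also hold peaks with weak support after correction. A −log10 q of 5 or more was reached by 53.7% of replicate 1 peaks, 55.8% of replicate 2 peaks and 89.0% of replicated peaks.

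Each peak carries a fold enrichment, deposited by the authors as a ratio in the narrowPeak signal column. Each also carries a −log10 p and a −log10 q, as the authors' deposited lists give them. These values were used within a list, to rank, describe or filter peaks. Fold enrichment was also correlated between the replicates. It was tested along the Hox clusters and, as a rank percentile, for genes marked in a single replicate. No read counts or coverage were used here, so depth and its effect on the number and width of peaks are unknown, and no count model was fitted.

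Peaks on chromosomes 1 to 19, X and Y were used. Peaks on other scaffolds, 54 in each replicate, 69 in the pooled list and 37 in the replicated list, were left out. The GRCm38 sequence and the GENCODE M21 annotation were used for start sites, exons and genes, with RefSeq for the checks of domains without a start site, and coordinates are 1-based on mm10. Overlaps were computed with bedtools 2.31.1 and sequences read with samtools 1.23.1 and pysam 0.24.0, and statistics with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. A peak counted as shared when at least 50% of its length lay under peaks of the other list. Random expectations came from 100 circular shifts of a list along each chromosome. A start-site window was 1000 bp either side of any annotated transcript start, and a gene was marked when a peak overlapped it by 1 bp or more. Domains joined peaks with gaps of 1000 bp or less, and a gene's domain was the widest that overlapped one of its windows. A window was CpG-rich with an observed over expected CpG ratio of 0.6 or more and a GC content of 50% or more.

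The study has a single group, so no comparison between conditions was made and the replicates were compared with each other. Gene lists were tested for marked members by Fisher's exact test (two-sided) against all other protein-coding genes, and for the median domain width of marked members by a permutation test with 100000 random sets of the same size, for lists with at least 5 marked members. Both were adjusted by the Benjamini-Hochberg method over lists, with 0.05 as the threshold. Genes, and genes that share a domain most of all, are not independent replicates, so these p-values describe the peak list of this tissue and not the variation between embryos. Values of the replicates are given as mean ± SD with n = 2, and pooled and replicated lists have no SD. Intervals are exact (Clopper-Pearson) 95% binomial intervals for counting error only.

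The gene lists, main tests, alternatives and the rule for named genes were fixed before the data were examined. Tests under other observations were added later, as stated there. The gene lists cover neural and neighbouring cell types, distant lineages, pathways and general functions, and olfactory and vomeronasal receptors were taken by symbol. All symbols were found in the annotation. The text names the 20 protein-coding genes with the widest domains, up to 4 marked members with the widest domain and up to 4 unmarked members in alphabetical order for each list, the 10 genes with the highest fold enrichment at a start site, the 10 genes marked in a single replicate with the highest rank percentile, all Hox genes and sex-linked controls, and the 5 widest domains without a start site. Partner genes of shared domains are named where they bear on these.

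Alternatives were overlaps of 1 bp and of 50% of both peaks, peaks with −log10 q of 5 or more, the 20000 strongest peaks by −log10 p, joined domains in place of peaks, windows of 500 and 2500 bp, the outermost start site of each gene, the pooled list, each replicate's own list, CpG-rich genes alone as background, joining distances of 0, 500 and 3000 bp, and random sets matched on 10 classes of CpG content or on the number of start sites. Counting each domain once was added after the data were seen. The procedures were tested on simulated data. With 20, 60 or 90% of the replicate 1 peaks left in place, the overlap procedure gave 20.0, 60.0 and 90.0%, and peaks placed at start sites of 200 genes marked all 200. Moved peaks that touched a real peak were removed, so these outcomes were fixed by the simulation and check the counting only. Of 200 random lists of 25 genes, 3.5% were called by Fisher's exact test and 6.5% by the width test, which called 91.5% of lists with widths multiplied by 1.5 and 100% of those with widths multiplied by 2.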

Results

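Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of promoters, was mapped by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos on embryonic day 12.5. The neural tube is the embryonic forerunner of the brain and spinal cord. The sample descriptions name the tissue only as neural tube, so how much of the brain it included is not known here. Both libraries belonged to 1 group, and the tissue behind them was pooled from 120 embryos for replicate 1 and from 88 embryos for replicate 2, with males and females mixed. The data were 4 peak lists on the mm10 assembly: a list for each replicate, a pooled list made from both, and a list of replicated peaks. No second tissue, stage or treatment was included, so the comparisons were between the replicates, between the peaks and the annotation, and between groups of genes. The lists carry no read counts, so the sequencing depth behind each peak is unknown. Each peak's fold enrichment is the authors' own value and was used to rank or describe peaks within a list. Beyond that it was correlated between the replicates and tested along the Hox clusters.

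The first question was how far the separate embryo pools gave the same peaks. Replicate 1 had 33549 peaks covering 30.1 Mb of the assembled chromosomes, with a median width of 505 bp, and replicate 2 had 33805 peaks covering 31.7 Mb, with a median width of 534 bp. Of the 33495 replicate 1 peaks on assembled chromosomes, 22561 (67.4%, exact binomial 95% interval 66.9 to 67.9%) had at least 50% of their length under replicate 2 peaks. In the other direction the share was 21059 of 33751 (62.4%, 61.9 to 62.9%). These intervals cover counting error only. When the other list was moved by random offsets along each chromosome, the share averaged 1.24% and 1.17% and never exceeded 1.47% in 100 shifts, so the overlap was above every shift (permutation p = 0.0099, the smallest that 100 shifts can give).

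Agreement between the replicates depended on the strength of the peaks. Each list was ranked by fold enrichment and split into 10 bins of equal size. The 3 bins with the highest values were shared in full, and in the next bin 99.97% of replicate 1 peaks and 99.9% of replicate 2 peaks were shared. In the lowest bin the shares were 20.0% and 11.6%. Unshared peaks were short and weak: their median width was 195 bp in replicate 1 and 205 bp in replicate 2, against 1063 and 1197 bp for shared peaks, and their median fold enrichment was 3.02 and 3.03, against 13.2 and 17.3. Across the 21184 pairs of mutually overlapping peaks, Spearman's correlation between the replicates was 0.951 for fold enrichment and 0.942 for width. These correlations are across peaks, which are not independent replicates. Altogether 26.2 Mb of the 35.5 Mb covered by either list was covered by both.

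**Figure D1:**
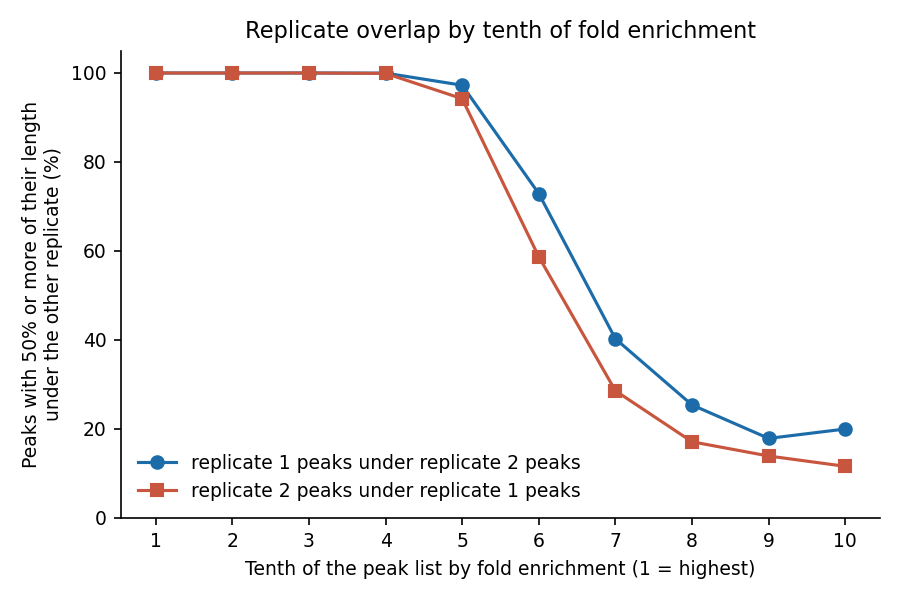
Percent of peaks with 50% or more of their length under the other replicate's peaks (y axis), in 10 equal bins of the list ranked on fold enrichment (x axis, bin 1 is the highest), for replicate 1 peaks (circles) and replicate 2 peaks (squares). Both lines stay at 99.9% or more through bin 4 and fall to 20.0% and 11.6% in bin 10.

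The list of replicated peaks, used below for the genes, held 22132 peaks, of which 22095 were on assembled chromosomes. It covered 32.2 Mb, and its peaks had a median width of 1278 bp and a median fold enrichment of 16.9. Each of these 22095 peaks had the coordinates of a pooled peak, and together they made up 66.5% of the 33241 pooled peaks (exact binomial 95% interval 66.0 to 67.0%). The other 11146 pooled peaks had a median fold enrichment of 2.67 and a median width of 210 bp, and 41.1% of them lay within 1000 bp of a replicated peak. Of the replicated peaks, 90.7% had at least 50% of their length under replicate 1 peaks, 94.5% under replicate 2 peaks and 86.6% under both. The remaining 2964 replicated peaks were therefore not covered to 50% in both lists. Of the 11146 other pooled peaks, 0 were covered to 50% in both lists. Such coverage thus always went with replication here but was not required for it. The rule by which the authors called a peak replicated is not given in the sources used here.

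H3K4me3 was concentrated at annotated transcription start sites. Of the replicated peaks, 16648 (75.3%) overlapped a window of 1000 bp either side of a start site in the GENCODE M21 annotation, against 9.93% on average and 11% at most in 100 random shifts (permutation p = 0.0099, the smallest possible). A further 5.11% overlapped an exon, 9.0% an intron and 10.5% no annotated gene, against shifted averages of 8.79, 31.7 and 49.6%. Peaks at start sites had a median width of 1564 bp and a median fold enrichment of 25.1, while those elsewhere had 539 bp and 4.29. The share at start sites was lower in lists that were not filtered for replication: 60.4% in replicate 1, 59.6% in replicate 2 and 59.7% in the pooled list.

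Peaks separated by 1000 bp or less were joined into domains, and a protein-coding gene was called marked when a replicated peak overlapped the window around any of its start sites. By this rule 14289 of 21911 protein-coding genes (65.2%) were marked. Replicate 1 marked 14424 genes and replicate 2 marked 14490, and 14234 of the 14680 genes marked in either list (97.0%) were marked in both. Nearly all genes with a CpG-rich start site were marked, while the others were split: 7479 of 7510 genes with a CpG-rich window (99.6%) were marked, against 6810 of the 14401 others (47.3%). The median domain at a marked gene was 1907 bp wide, and 5% of marked genes had a domain wider than 4467 bp. Across genes marked in both replicates, Spearman's correlation of domain width was 0.895, with genes not being independent replicates. The highest fold enrichment at a start site was found at Arid1a (chromosome 4, 133749809 to 133757856), which encodes a subunit of the SWI/SNF chromatin remodelling complex. The next were the divergent neighbours Alyref and Anapc11 (65.5 for their shared domain), Map7d1 (65.2), Wdr26 (64.6), the splicing factor gene Sfpq (64.3), Yrdc with its neighbour 1110065P20Rik (64.1), Mark3 (64.1) and Ankrd11 (63.8).

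The next question was which groups of genes carried the mark in this tissue. Genes of neural progenitors and of neurons in general were marked almost without exception. All 20 neural progenitor genes carried a replicated peak (adjusted p = 0.000489, Fisher's exact test, two-sided, against all other protein-coding genes, Benjamini-Hochberg over 25 lists), among them Pax6, Zic1 and Zic2, which encode transcription factors, and Msi1, which encodes an RNA-binding protein of neural stem cells. All 35 transcription factors of spinal neuron subtypes were marked (exact test, adjusted p = 4.25e-06), including Lhx1, Lhx5 and Lmx1b of dorsal interneurons and Skor1. So were all 29 pan-neuronal genes (exact test, adjusted p = 1.46e-05), such as Elavl2 and Elavl4 of the neuronal RNA-binding proteins, all 30 synaptic and late neuronal genes (adjusted p = 1.13e-05), such as the glycine receptor gene Glra1 and the glutamate receptor gene Grin2a, and all 20 floor plate and roof plate genes (adjusted p = 0.000489), such as Ntn1, Slit2, Bmp4 and Msx2. Of 25 dorsoventral progenitor transcription factors 23 were marked (exact test, adjusted p = 0.0044). The unmarked members were Dbx1 and Dbx2, which are expressed in the intermediate progenitor domains of the spinal cord. Neither had a peak at a start site in either replicate's list. In the pooled list, and with windows of 2500 bp, 24 of the 25 were marked and 1 was not. Transcription factors of the forebrain and midbrain were also marked in 25 of 27 cases (exact test, adjusted p = 0.00307), among them Bcl11b, Satb2, Lhx6 and Dlx2. Six6 was unmarked in both replicates, and Neurod6 was marked in replicate 1 only. In the pooled list all 27 were marked. For the forebrain and midbrain factors the call was lost with the outermost start site alone (exact test, adjusted p = 0.155). It was also lost with peaks of −log10 q of 5 or more (exact test, adjusted p = 0.217), where 77.8% of the members were marked.

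Genes used for specific transmitters or by later glia were marked in part. Of 19 neurotransmitter identity genes 13 were marked (exact test, adjusted p = 1), with Slc32a1, Gad1 and Slc6a5 of GABAergic and glycinergic neurons and Slc17a6 of glutamatergic neurons among them and Dbh, Ddc, Hdc and Slc17a8 unmarked. Of 28 oligodendrocyte and astrocyte genes 16 were marked (exact test, adjusted p = 0.465). Nfib, Nfia, Pdgfra and the glutamate transporter gene Slc1a2 had domains of 13858 bp, 5486 bp, 9596 bp and 4712 bp, whereas Aqp4, Aspa and Ermn were unmarked in both replicates and Aldoc was marked in replicate 2 only.

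Genes of cell types that can adjoin the neural tube were marked in part, and none of these lists differed from other genes at the main settings. With windows of 2500 bp, neural crest and sensory ganglion genes passed the threshold (exact test, adjusted p = 0.0409). Of 24 neural crest and sensory ganglion genes 20 were marked (exact test, adjusted p = 0.117), with Tfap2a, Tfap2b, Foxd3 and Six1 among them and Avil, Phox2b, Scn10a and Scn11a unmarked. Sclerotome, cartilage and connective tissue genes were marked in 17 of 21 cases (exact test, adjusted p = 0.212), with the transcription factor genes Foxc1, Foxc2, Prrx1 and Twist1 marked and the matrix genes Dcn, Lum and Matn1 unmarked. Endothelial genes were marked in 14 of 20 cases (exact test, adjusted p = 0.85), including Fli1 and Esam and excluding Cdh5 and Pecam1, and skeletal muscle and somite genes in 10 of 20 (adjusted p = 0.212). In that last list Lbx1 and Six1, which are also in the spinal neuron and sensory lists, were marked, while the myogenic factor genes Myf5 and Myf6 and the actin gene Acta1 were unmarked. The marked muscle gene Mylpf shares its domain with Tbc1d10b. Heart genes, of a lineage distant from the neural tube, were marked in 10 of 19 cases (exact test, adjusted p = 0.38). They were called less often marked with peaks of −log10 q of 5 or more (exact test, adjusted p = 0.0228) and with the outermost start site (adjusted p = 0.0489).

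Genes of distant lineages other than heart were marked less often than other genes. Among blood and microglial genes 3 of 25 were marked (adjusted p = 5.84e-07, Fisher's exact test), and these were Klf1, Gypa and Epor of red blood cell precursors, while Aif1, C1qa, C1qb and Alas2 were unmarked. The count was 5 in the list of replicate 1, 4 in that of replicate 2 and 6 in the pooled list. Of 21 epidermal and keratin genes 3 were marked (exact test, adjusted p = 1.11e-05), namely Krt1, Krt10 and Grhl3. Of 24 liver, gut and pancreas genes 6 were marked (exact test, adjusted p = 0.000257), with Onecut1, Hnf1b and Cdx1 marked and Afp, Alb, Apoa1 and Apoa2 unmarked. Foxa3, also marked, shares its domain with Sympk. Pluripotency and germ line genes were marked in 5 of 20 cases (exact test, adjusted p = 0.000854), among them Esrrb, Nanos3, Prdm9 and Dmrt1. Of 1418 olfactory and vomeronasal receptor genes 3 were marked (0.212%, exact binomial 95% interval 0.0437 to 0.617%): Olfr94, Olfr658 and Vmn1r4, the last of which shares its domain with Nt5c3. The list of replicate 1 marked 6 of these receptors, and replicate 2 and the pooled list marked 4 each.

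Signalling and general cell functions were marked throughout, apart from the retinoid pathway. All 15 hedgehog pathway genes (adjusted p = 0.00326), all 21 Notch pathway genes (adjusted p = 0.000489), all 30 housekeeping genes (adjusted p = 1.13e-05) and all 29 replication and cell cycle genes (adjusted p = 1.46e-05) were marked, by the same Fisher's exact test. Retinoid pathway genes were marked in 14 of 18 cases (exact test, adjusted p = 0.38). Their unmarked members were Aldh1a1, Rbp1, Stra6, which was marked in replicate 1 only, and Cyp26c1, which was marked in each replicate's own list. The test treats genes as independent, which they are not, and describes this peak list. Among genes with CpG-rich start sites, where 99.6% of all genes were marked, no list was marked more often than the rest and only the list of pluripotency and germ line genes was marked less often.

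**Figure D2:**
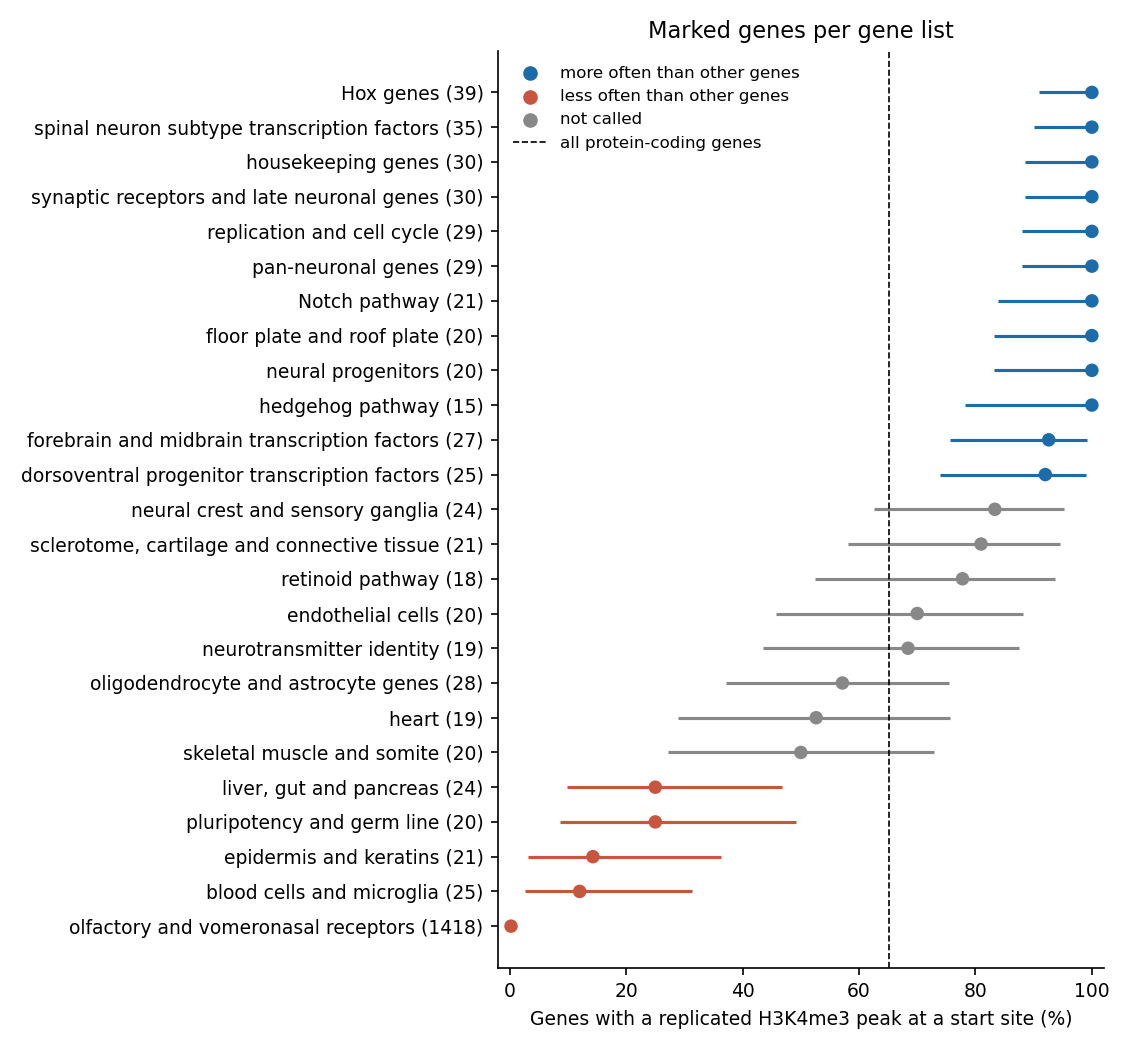
Percent of the genes of each list with a replicated H3K4me3 peak at a start site (x axis), with list size in parentheses and bars for exact binomial 95% intervals. Blue and red lists were marked more or less often than other genes by Fisher's exact test after adjustment, grey lists were not called, and the dashed line marks all protein-coding genes (65.2%); 10 lists stand at 100%, and the olfactory and vomeronasal receptors stand at 0.212%.

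Among marked genes, those of most neural lists lay in domains wider than usual. Neural progenitor genes had a median domain of 6727.5 bp, against 1907 bp for all marked genes (adjusted p = 5.5e-05, the smallest obtained; permutation test against 100000 random sets of marked genes, two-sided, Benjamini-Hochberg over 22 lists). The list's median in the replicates' own peaks was 6246.5 ± 196 bp (SD, n = 2). The widest of them were Pax6 (chromosome 2, 105668462 to 105684080; 15619 bp, 15811 ± 407 bp in the replicates), Zic2 (13996 bp, 11316 ± 12.7 bp in the replicates), Zic1 (12480 bp, 10851 ± 2878 bp in the replicates) and Msi1 (11150 bp, 11442.5 ± 36.1 bp in the replicates), all as mean ± SD with n = 2. Spinal neuron transcription factors had a median of 4556 bp (4017 ± 368 bp in the replicates), led by Lhx5 (chromosome 5, 120424050 to 120440826; 16777 bp, 16673.5 ± 50.2 bp in the replicates), Lhx1 (16036 bp, 17592.5 ± 4765 bp in the replicates), Skor1 (13196 bp, 12920 ± 1068 bp in the replicates) and Lmx1b (11319 bp, 10313.5 ± 2427 bp in the replicates). Pan-neuronal genes had 3631 bp (3707.5 ± 436 bp), with Crmp1 at 7781 bp and Elavl4 at 7492 bp, dorsoventral progenitor factors 3521 bp (3405 ± 895 bp), with Pax3 at 17600 bp (chromosome 1, 78186869 to 78204468) and Irx5 at 12282 bp, and floor plate and roof plate genes 3304 bp (3132.5 ± 386 bp), with Bmp4 at 5488 bp. Marked neurotransmitter genes had 4925 bp, with Slc32a1, the vesicular transporter of GABA and glycine, at 11278 bp (11269.5 ± 121 bp), Slc6a5 at 8807 bp and Gad1 at 8777 bp. The replicates differed for this list, with medians of 2701 and 5703 bp. Synaptic and late neuronal genes were wider by less (2655.5 bp, adjusted p = 0.00311, permutation test). The other neural lists called wider had adjusted p values of 5.5e-05, or 9.78e-05 for floor plate and roof plate, in the same permutation test.

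Outside the neural lists, the Hox genes had the largest median of any list when each gene was counted (median 26197 bp, 28997 ± 7348 bp in the replicates, adjusted p = 5.5e-05, permutation test), and their 39 genes shared 21 domains. With each of these domains counted once, a choice made after the data were seen, the median was 5862 bp, below the 6727.5 bp of neural progenitors, and the list was still wider than random domains (adjusted p = 6.29e-05, permutation test). The median also depended on the joining distance, with 6728 bp without joining and 68618 bp when gaps up to 3000 bp were joined, and was 61955 bp in the pooled list. Genes of the hedgehog pathway (4169 bp), with Ptch1, the receptor of the ligand, at 7307 bp, of the Notch pathway (4075 bp), with Dll1 at 8607 bp and Hes1 at 8123 bp, and of the retinoid pathway (3684 bp), with the receptor gene Rara at 12273 bp, were also wider than random sets (adjusted p = 5.5e-05, 5.5e-05 and 0.000132, permutation test). The Notch genes Dll1, Hes1 and Hes5 are also in the neural progenitor list, and Shh of the hedgehog list is also in the floor plate and roof plate list. The Notch and hedgehog lists are therefore not separate from the neural ones. Rxrb, the next widest retinoid gene at 9536 bp, shares its domain with H2-Ke6, Ring1 and Slc39a7. Sclerotome, cartilage and connective tissue genes had a median of 2925 bp (permutation test, adjusted p = 0.00393), with Foxc1 at 6803 bp and Foxc2 at 6250 bp, and housekeeping genes 2764.5 bp (adjusted p = 0.00108), with Eef2 at 4936 bp. Heart genes were narrower (1015 bp, permutation test, adjusted p = 0.00183), with Gata6 at 3054 bp and Hand2 at 1478 bp. Their call was lost with peaks of −log10 q of 5 or more (permutation test, adjusted p = 0.312), and the median turned above random sets when gaps up to 3000 bp were joined (adjusted p = 0.129).

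For 8 lists the median did not differ from random sets at the main settings. Neural crest and sensory ganglion genes had 2485 bp (adjusted p = 0.0563, permutation test), with Tfap2a at 12348 bp (chromosome 13, 40722509 to 40734856) and Foxd3 at 10147 bp, and replication and cell cycle genes 2341 bp (adjusted p = 0.0809), with Ccnd2 at 8008 bp. Both lists were called wider in some alternatives, among them with each domain counted once (adjusted p = 0.0346 and 0.0452, permutation test). Forebrain and midbrain transcription factors had 1751 bp (permutation test, adjusted p = 0.556), with Bcl11b at 8428 bp and Satb2 at 4544 bp and the others at 3379 bp or less. They were narrower than random sets matched on CpG content (adjusted p = 0.0334, permutation test). With joining distances of 0 and 500 bp they were also narrower than random sets (adjusted p = 0.000176 and 0.00022, permutation test). In the pooled list their median was above that of random sets (adjusted p = 0.618, permutation test). Medians were 1922 bp for oligodendrocyte and astrocyte genes, 1938.5 bp for endothelial genes, 1877 bp for pluripotency and germ line genes, 1695 bp for skeletal muscle and somite genes and 1541 bp for liver, gut and pancreas genes (adjusted p from 0.397 to 0.961). The liver, gut and pancreas list, with 6 marked genes, depended on the setting: it was narrower than random sets without joining (1061.5 bp, adjusted p = 0.0309, permutation test) and in the list of replicate 1 (884 bp), and above them in that of replicate 2 (2074 bp). The lists with fewer than 5 marked members, blood and microglia, epidermis and olfactory receptors, were not tested. Widths are those of the peaks above the authors' threshold after joining, so they also depend on the unknown depth.

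**Figure D3:**
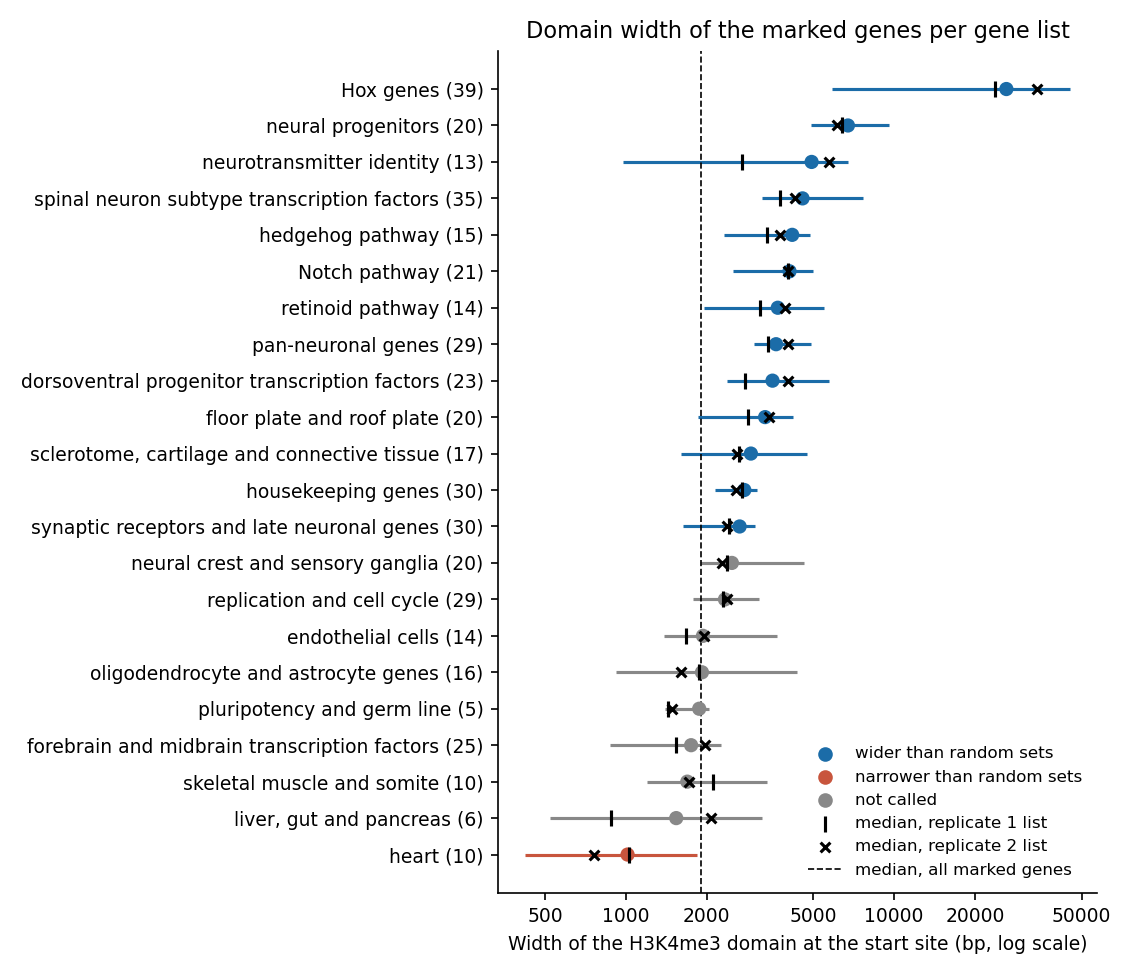
Width in bp of the H3K4me3 domain at the start sites of marked genes per list (x axis, log scale), with the number of marked genes in parentheses; points are medians in replicated peaks, bars span the interquartile range, and ticks and crosses are the medians in replicate 1 and replicate 2. Blue lists were wider and red lists narrower than random sets of marked genes, and the dashed line marks the median of all marked genes (1907 bp); Hox genes (26197 bp) and neural progenitors (6727.5 bp) lie farthest to the right.

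The 4 Hox clusters, whose genes are expressed in overlapping stretches along the body axis, were covered by long runs of H3K4me3 peaks. All 39 Hox genes were marked in the replicated list, which left Fisher's exact test of paralogue groups 1 to 9 (27 genes) against 10 to 13 (12 genes) without a difference to test (p = 1). Replicated peaks covered 80.3% of HoxA (76.1 ± 0.305% in the replicates, SD, n = 2) and 73.7% of HoxC (67.1 ± 4.12%). They covered 65.2% of HoxD (60.5 ± 3.4%) and 53.7% of HoxB (52.3 ± 0.797%). Each cluster was counted from the outer ends of the first and last gene. The HoxB span included a stretch between the domains of Hoxb13 and Hoxb9, from 96203579 to 96250642, that held no replicated peak. The lower share of HoxB therefore depends on where the span was drawn. In the replicated list the widest domain at any protein-coding start site lay in HoxB (chromosome 11, 96268483 to 96346836), ran without a gap over 1000 bp for 78354 bp (78256 ± 52.3 bp in the replicates) and held the start sites of Hoxb3 to Hoxb9. The next was a domain of 45103 bp in HoxA (chromosome 6, 52196196 to 52241298) holding Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Gm28308. In HoxC, Hoxc4, Hoxc5, Hoxc6 and Hoxc8 shared 39209 bp (chromosome 15, 102989499 to 103028707), and Hoxc9 and Hoxc10 shared 28554 bp. These genes filled all 20 places at the head of the width ranking. In the pooled list the order differed, with a domain of 89.9 kb in HoxC against 78.4 kb in HoxB. The group 13 genes had short domains, with 1754 bp at Hoxa13, 658 bp at Hoxb13, 1887 bp at Hoxc13 and 1428 bp at Hoxd13.

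**Figure D4:**
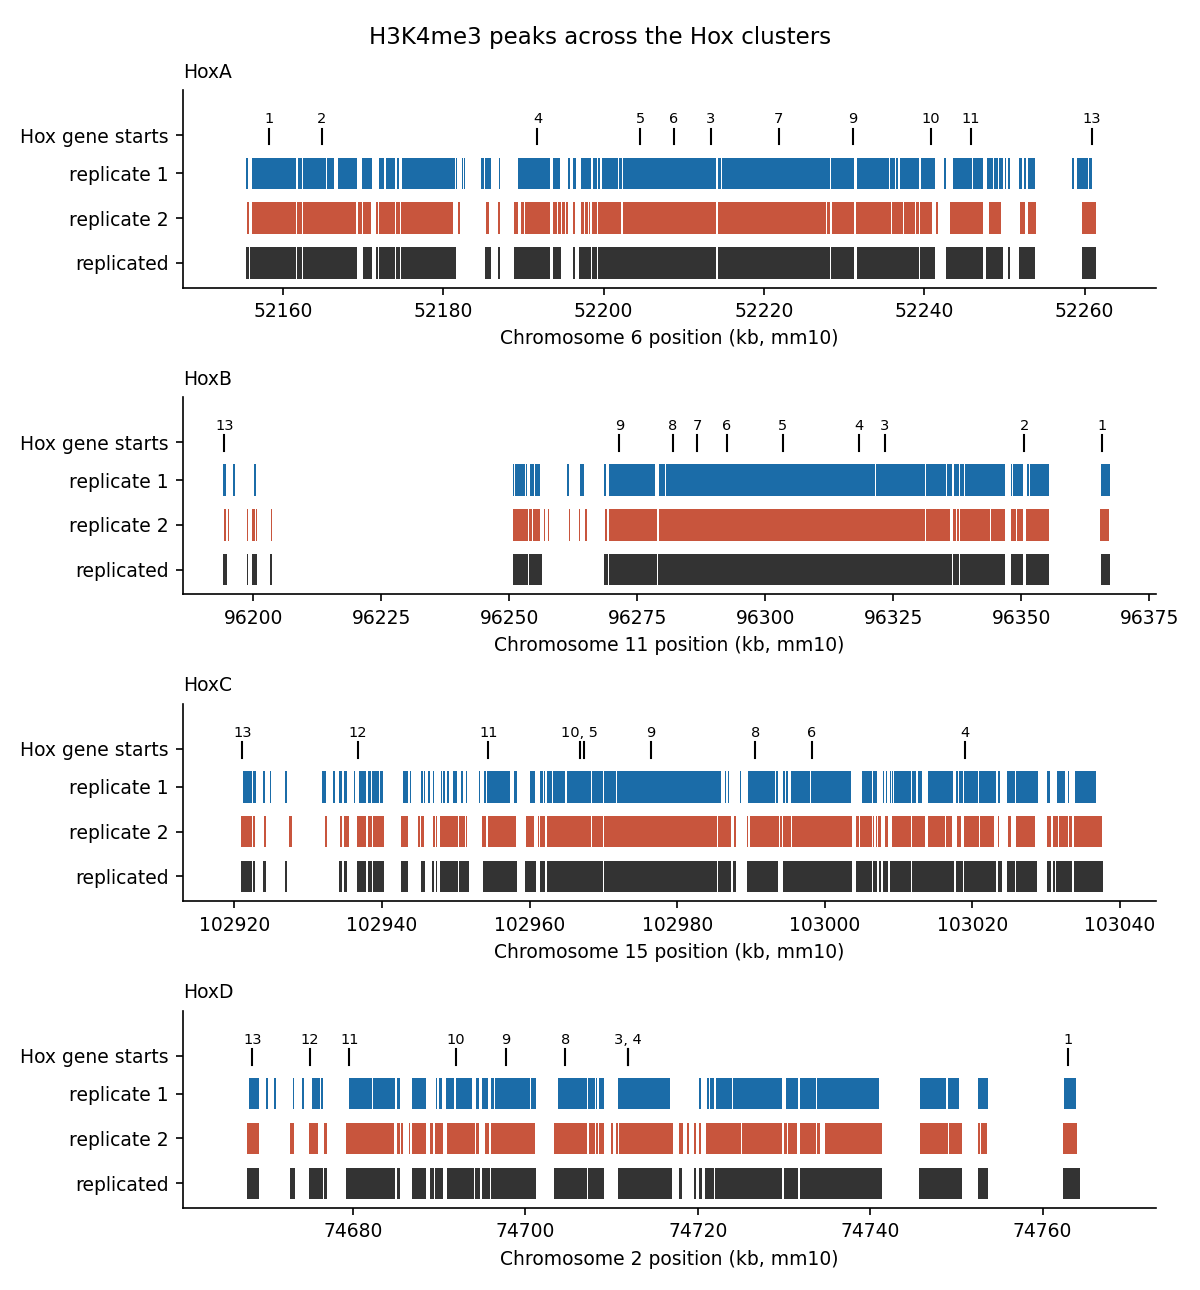
H3K4me3 peaks of replicate 1, replicate 2 and the replicated list (bars) across the HoxA, HoxB, HoxC and HoxD clusters, by chromosome position in kb on mm10 (x axis), with the outermost start of each Hox gene marked by its paralogue number. The long run of peaks in HoxB, with gaps of at most 1000 bp, is the domain of 78354 bp from Hoxb3 to Hoxb9, and the group 13 genes of each cluster stand on short separate domains.

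Few genes were marked in a single replicate. Replicate 1 marked 190 genes that replicate 2 did not (1.32% of its marked genes), and replicate 2 marked 256 that replicate 1 did not (1.77%). The peaks behind these genes were weak within their own list: their median rank percentile by fold enrichment was 25.6 and 22.6, against 80.5 and 80.7 for random sets of marked genes (p = 2e-05 for each, the smallest that 100000 draws can give, permutation test, two-sided). These genes were selected for lacking a peak in the other list, and the strongest bins of peaks were shared in full. Low percentiles therefore follow largely from the selection, and the p-value adds no separate support. The median domain of these genes was 220 and 226.5 bp wide, and 2.11% and 1.95% of them had CpG-rich start sites, against 51.9% and 51.6% of all marked genes. Among the strongest, Sftpc was marked in replicate 1 at percentile 94.6 through a domain shared with Bmp1, and Lmntd2 (81.9) and Adam8 (72.7) were marked in replicate 2 through domains shared with Rassf7 and 6430531B16Rik; all 3 were also marked in the replicated list. The next were Tmem88b (70.3), Hrc (66.3) and Ccdc8 (61.1) in replicate 1, and Fam162b (53.6), Slc26a5 (53.6), 4930519G04Rik (53.1) and Gm9936 (53.1) in replicate 2. The sex-linked control genes were marked in both pools. Xist on the X chromosome had a domain of 2034 bp in the replicated list, and the Y-linked genes Kdm5d (1025 bp), Uty (954 bp), Ddx3y (928 bp) and Eif2s3y (736 bp) were marked in each replicate.

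Of the 18629 replicated domains, 14969 (80.4%) overlapped the window of an annotated start site, with a median width of 1746 bp, and 3660 did not, with a median width of 605 bp. The 5 widest domains without a GENCODE start site lay on chromosome 13 from 21166737 to 21173541 (6805 bp, intergenic, nearest GENCODE start site that of Trim27 at 5903 bp, with 1 RefSeq start and 7 tRNA gene starts within 1000 bp), on chromosome 2 from 115854574 to 115861180 (6607 bp, intergenic, 7686 bp from a start site of the homeobox gene Meis2), on chromosome 11 from 119053000 to 119059090 (6091 bp, intergenic, 12031 bp from Cbx8), on chromosome 15 from 85676245 to 85681521 (5277 bp, in an intron of the non-coding gene Lncppara) and on chromosome 1 from 172012868 to 172018087 (5220 bp, over an exon of Vangl2, a planar cell polarity gene, with 2 RefSeq starts within 1000 bp). Their highest peaks had fold enrichments of 19.3, 5.54, 22.9, 4.46 and 4.02.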

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

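Of 495 alternative values, 401 were classed as the same. Tests had to keep their direction and side of the threshold. Shares had to stay within the counting interval or spread of the main value, and counts within a fixed factor of the main count. The alternative that counts each domain once was chosen after the data were seen. Causes were not tested unless a sentence states one.

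The overlap of the replicates depended most on the weak peaks. The share of replicate 1 and replicate 2 peaks under the other list was 71.4 and 67.5% with 1 bp of overlap, 56.7 and 56.3% with 50% of both peaks, 96.1 and 89.6% with −log10 q of 5 or more, 92.4 and 88.9% for the 20000 strongest peaks, and 70.6 and 68.2% for joined domains. Of pooled peaks with −log10 q of 5 or more, 98.8% were replicated. Replicated peaks lay under both replicates in 92.9% of cases with 1 bp, 81.8% with 50% of both peaks and 93.8% with −log10 q of 5 or more. The share of peaks at start sites was 71.9% and 82.7% with windows of 500 and 2500 bp, 80.3% with −log10 q of 5 or more, 59.7% in the pooled list and 59.6 to 60.4% without either replicate. Coverage in the pooled list was 83.4% of HoxA, 55.5% of HoxB and 78.3% of HoxC, and without either replicate it was 75.9 to 76.3% of HoxA, 51.7 to 52.8% of HoxB, 64.2 to 70.1% of HoxC and 58.1 to 62.9% of HoxD. With −log10 q of 5 or more in both lists, 90 genes were marked in replicate 1 only.

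Restricting the occupancy test to genes with CpG-rich start sites ended every call for a list marked more often (0 lists) and left 1 list marked less often. In that background 99.6% of genes are marked, which leaves no room for a higher share: 100% were marked among neural progenitors, floor plate and roof plate, spinal neuron, pan-neuronal, synaptic, forebrain and midbrain, Hox, hedgehog, Notch, housekeeping and cell cycle genes (weaker). The share turned to the other side of the background at 93.8% for dorsoventral factors and 100% for glial, muscle, heart, liver and olfactory receptor genes, without a call. Blood and epidermal lists have no CpG-rich member and gave no value. Forebrain and midbrain factors lost their call at 77.8% with the outermost start site and at 77.8% with −log10 q of 5 or more, where heart genes became less often marked (36.8% in each). Neural crest genes passed the threshold at 87.5% with windows of 2500 bp. The few marked blood and microglial genes (12%) became 20% without replicate 2 and 24% in the pooled list, and receptor genes (0.212%) became 0.423% without replicate 2 and 0.141% with the outermost start site. Endothelial genes turned below the background at 55.0% with windows of 500 bp and 60% with −log10 q of 5 or more, without a call.

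The lists called wider kept that call in every alternative run, but their medians depended on the joining distance. With 0 and 3000 bp the median was 6728 and 68618 bp for Hox genes (26197 bp in the main result), 2456 and 7602 bp for spinal neuron factors (4556 bp) and 2489 and 6016 bp for dorsoventral factors (3521 bp). With 0 bp it was 2583 bp for hedgehog genes (4169 bp) and 2975 bp for neurotransmitter genes (4925 bp), which had 2701 bp without replicate 2. Hox genes had 61955 bp in the pooled list, where the widest domain of HoxC grew from 39.2 to 89.9 kb and passed that of HoxB (78.4 kb), and 5862 bp with each domain counted once, below neural progenitors (6727.5 bp). The lists called narrower numbered 3 with joining distances of 0 and 500 bp, 0 with 3000 bp, 0 with −log10 q of 5 or more, 2 in the pooled list, 2 with sets matched on CpG and 1 to 4 without either replicate. Forebrain and midbrain factors became narrower than random sets with distances of 0 bp (median 1060 bp) and 500 bp (1139 bp) and with CpG-matched sets (1751 bp against 2158 bp), and lay above them without a call with 3000 bp (2318 bp), in the pooled list (2140 bp) and without replicate 1 (range 1536 to 1964.5 bp). Heart genes lost the call with −log10 q of 5 or more (1478 bp) and turned wider with 3000 bp (2788.5 bp). Liver genes became narrower with 0 and 500 bp (1061.5 bp in each) and turned with 3000 bp (2123.5 bp), and they were narrower without replicate 2 (884 bp) and lay above random sets without replicate 1 (2074 bp against 1862 bp). Neural crest genes became wider with 3000 bp (3749 bp), with each domain counted once (2485 bp) and without replicate 2 (range 2283.5 to 2378.5 bp), and cell cycle genes with each domain counted once (2341 bp) and without either replicate (2298 to 2387 bp). Lists near the random median changed side without a call: glial genes with 3000 bp (1922 bp), in the pooled list (1838 bp), with sets matched on start sites (1922 bp) and without replicate 1 (range 1601 to 1878 bp), muscle genes with 3000 bp (2566.5 bp) and without replicate 2 (range 1726 to 2114 bp), endothelial genes with 0 bp (1776 bp), with −log10 q of 5 or more (1884.5 bp) and without replicate 2 (range 1669.5 to 1960 bp), and pluripotency genes with 0 bp (1875 bp), CpG-matched sets (1877 bp) and each domain counted once (1877 bp). Without read depth, it cannot be said how many weak peaks a deeper library would add.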

Other observations

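The test of forebrain against spinal factors, the Hox trend and the tRNA gene count were chosen after related values were seen, and so was the use of the matched sets and of unjoined peaks, both fixed before the data were examined, to weigh explanations of the wide neural domains. Although every Hox gene was marked, the strength of the mark differed along the clusters. The fold enrichment of the peak at a gene's outermost start site fell with paralogue number (Spearman's rho -0.534 across 39 genes, permutation p = 0.00048, genes that share peaks not being independent). Its median was 40.9 in groups 1 to 9 and 12.4 in groups 10 to 13. It was highest at Hoxb2 (55.4), followed by Hoxb3 to Hoxb8, which share a peak (53.9), and lowest at Hoxd12 (5.46), Hoxb13 (5.54) and Hoxa13 (7.86). The anterior genes were not uniformly high, with 10.4 at Hoxb1 and 9.66 at Hoxc4. The median domain width was 39209 bp in groups 1 to 9 and 4127 bp in groups 10 to 13, with a weaker trend (rho -0.333, permutation p = 0.0392). The 39209 bp is the width of a single domain shared by Hoxc4, Hoxc5, Hoxc6 and Hoxc8. The 39 genes shared 21 domains, some of which held genes of both ranges, and the permutation treated each gene as independent. The trend in width was not tested with each domain counted once, so this p-value gives it little support.

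Many transfer RNA genes, which are transcribed by RNA polymerase III, lay in H3K4me3 domains. Of 403 tRNA gene starts in the RefSeq annotation of the same assembly, 187 (46.4%) lay in a replicated domain, and of the 359 more than 1000 bp from a protein-coding start, 153 did (42.6%). The widest domain without a GENCODE start site, on chromosome 13 near Trim27, holds 7 tRNA gene starts and 1 other RefSeq start in its 1000 bp window. Among non-coding genes whose outermost start is away from protein-coding starts, 8.59% of lincRNA genes (470 of 5470) and 12.9% of antisense genes (247 of 1922) were marked, against 1.31% of processed pseudogenes (129 of 9823).

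The wide domains at neural genes were weighed against 3 technical explanations, and all 7 neural lists called wider kept their call in each permutation test. Their medians were 1.57 to 3.06 times those of random sets matched on CpG content of the start-site windows (largest adjusted p = 0.00012, permutation test) and 1.35 to 3.60 times those of sets matched on the number of annotated start sites per gene (largest adjusted p = 0.00471). Without the joining of neighbouring peaks into domains they were 1.36 to 2.55 times those of random sets (largest adjusted p = 0.014, permutation test), with 2456 bp in place of 4556 bp for spinal neuron factors, so joining sets part of the size. Each of these 3, taken alone, is argued against as the whole cause, and their combination was not tested. The CpG matching used the highest ratio among a gene's windows, so the length of a CpG-rich stretch beyond a window was not matched. Keeping the call was not particular to neural lists. Sclerotome, cartilage and connective tissue genes and housekeeping genes kept theirs in all 3 (largest adjusted p = 0.0457 and 0.014, permutation test). So did Hox, hedgehog, Notch and retinoid genes. Depth, enhancers next to the neural promoters and transcription in this tissue were not tested and stay open. A link between wide domains and genes in use in the neural tube is a hypothesis that may be tested with expression data.

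Forebrain and midbrain transcription factors were nearly all marked but had narrower domains than those of spinal neuron subtypes, with a median of 1751 bp for 25 genes against 4556 bp for 35 (difference 2805 bp, permutation p = 0.0001 with list labels exchanged) and a median fold enrichment of 9.11 against 12.1. Their CpG content was close, with median observed over expected ratios of 0.723 and 0.740, and the difference kept a permutation p = 0.00014 when labels were exchanged only within 5 classes of CpG content. It kept a permutation p = 6e-05 within classes of the number of start sites, although exchanged labels then gave a median difference of 906 bp (475 bp within CpG classes, 94 bp without classes), so these properties may go with part of it. Each property alone is argued against as the whole cause, and they were not tested together. A mark in few of the cells, or a mark held at genes that are not transcribed, could give narrow domains too. The peak lists of a mixed tissue hold no value that separates these, and how much of the brain the tissue included is not known here.

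The 3660 replicated domains without an annotated start site were set against 3 explanations, whose tests were written down before their results were seen. A RefSeq transcript start missing from GENCODE M21 lay within 1000 bp of 12.6% of them (exact binomial 95% interval 11.5 to 13.7%), against 5.09% on average in shifted lists. A tRNA gene start did so for 2.43% (1.96 to 2.98%), against 0.0317%, and a domain with a start site lay within 5000 bp of 19.7% (18.4 to 21.1%), against 7.45%. Shifted domains could also meet RefSeq starts that GENCODE holds, which the 3660 domains by definition could not. The 5.09% is therefore not the rate for missing starts alone. Shifted domains could likewise fall on a domain with a start site or within 1000 bp of it, where the 3660 domains could not lie. The 7.45% is therefore not the rate for outlying parts alone. Each share is above its highest value in 100 shifts and each interval lies below the 50% set as the bound, so each explanation may account for a part of these domains and none for most of them. For 2509 domains (68.6%) none of the 3 applied, and enhancers or unannotated start sites in this tissue remain open as untested explanations.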
